A study of Mus musculus with 2 samples.

How the data were processed

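RNA of single cells was measured by 3' tag sequencing in 2 libraries of mouse induced myogenic progenitor cells at passage 4, 1 from a MyoD-WT clone and 1 from a MyoD-KO clone. Per the labels, the cultures held forskolin at 5 µM, RepSox at 5 µM, CHIR99021 at 3 µM and bFGF at 10 ng/mL, and 12000 cells were used per library with about 10000 targeted. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 7.2.0 per the file headers. GRCm39 and Seurat are named in the submitters' processing notes without their roles, and the annotation release is not stated. The files list 25906 genes and 8191 WT and 7670 KO barcodes, and cell calling had already been applied to them. The reference at hand was RefSeq of GRCm38.p6, another build, so no coordinates are given and it served only for the order of genes around Myod1.

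Cells were kept with at least 1000 genes detected and at most 15% mitochondrial UMIs. In WT 577 barcodes had too few genes and 734 too many mitochondrial UMIs, 873 failing either, and in KO these numbers were 1111, 1187 and 1888. Doublets were called per library with Scrublet as run by scanpy 1.11.5 at an expected rate of 0.06. It called 192 of 5782 KO cells (3.32%) but 5 of 7318 WT cells (0.0683%), too few for its calls to be relied on in the WT library, and the labels do not say whether doublets were removed before deposit. The called cells were removed, and removing the 6% of cells with the highest scores in each library was added as an alternative after the data were seen, once with the other cells clustered and named again and once with their classes kept. This left 7313 WT cells (median 35512 UMIs) and 5590 KO cells (median 40353 UMIs).

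The kept cells of both libraries were clustered together on log-normalised values centred within each library, with 3000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9). Myod1, Myf5, Myog, Myf6, Pax3, Y-linked, mitochondrial, ribosomal protein, S phase and G2M list genes were left out of the clustering. Clusters were named from 13 marker sets fixed before the data were examined. Each cluster took the class with the highest mean marker level, each marker scaled from its lowest to its highest level over the clusters. It stayed unnamed where that mean was under 0.5 of this range, or where under 3 markers were detected in at least 10% of its cells. The same held where its median depth was under its library's median divided by 3, with no own marker among its 10 leading genes. Clusters 14, 15, 16 and 17 were that shallow, and 16 and 17, with means of 0.427 and 0.485, stayed unnamed. Classes with at least 100 cells in each library were compared for gene levels, which leaves out the fibroblast-like class.

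UMI counts were summed over the cells of a library, or of a library and class, and scaled to the same total (1e6 counts) to give CPM. CPM have exact 95% Poisson intervals, KO/WT ratios the interval conditional on the summed count, and shares of cells exact Clopper-Pearson intervals. A value of 0 is given the limit of 3 counts. The interval of a difference of 2 shares combines their exact bounds as in Newcombe's method. No test was made and no p-value is given, because cells are not replicates and each genotype has 1 clone. A gene counted as higher or lower when the libraries differed at least 2-fold and the higher had at least 10 CPM. For 36 gene lists fixed before the data were examined, holding 597 distinct genes of which 594 are in the files, the median log2 ratio was taken over members with a mean of at least 1 CPM. It was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart below the 2.5th or above the 97.5th percentile. The plan took list medians over all cells, and taking them within classes too was added. The percentile describes these 2 libraries and is not a p-value. Lists with under 3 members measured were not ranked. Of the symbols in the files, 18 belong to more than 1 gene, and those genes were kept apart by identifier.

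Shares of cells with a UMI and phase calls (scanpy's cell cycle scoring) were taken after thinning each cell to 5000 UMIs with a fixed seed. Genes are named by a rule fixed before the data were examined. It takes the 6 regulators, the 12 highest and 12 lowest KO/WT ratios among genes with at least 50 CPM in the higher library (6 and 6 within a class, without mitochondrial, ribosomal protein, Gm, Rik and sex-linked genes), and up to 4 members with the largest log2 ratio per list, with further members where a list goes both ways. Mki67, Top2a, the genes beside Myod1 and the X-linked genes are named outside this rule.

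The gene comparison was tested on simulated Poisson counts for the 25906 genes, of which 8241 had at least 10 CPM. The depths were those of all deposited barcodes, which lie above those of the kept cells compared. All 50 genes made 3-fold higher and all 50 made 3-fold lower passed the size rule, and none made 1.5-fold different and none unchanged did. Apart from these changes both libraries were drawn around a shared mean, with no variation between clones or libraries. The simulation thus checks the calculation and cannot show how often a call reflects such variation. The interval held the true ratio for 94.7% of genes with at least 20 CPM, and 5.50% of 200 lists with no shift stood apart.

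Alternatives were scaling by TMM factors from edgeR 4.0.16 in R 4.3.3, a total without mitochondrial and ribosomal protein genes, all deposited barcodes, the mean of the cells' own CPM, other expression minimums, WT class shares in both libraries, other clusterings, thinning to 2000 UMIs or not at all, and doublets kept. Removing the cells with the highest doublet scores, the fibroblast-like class or the shallow clusters, and class shares over all deposited barcodes, were added later. The remaining work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.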

Results

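Single-cell RNA profiles were collected from 2 clones of induced myogenic progenitor cells, a culture in which fibroblasts have been turned into proliferating, Pax7-positive muscle precursors that also form differentiated muscle cells. Mouse embryonic fibroblasts of the labelled genotypes MyoD-WT (WT) or MyoD-KO (KO) were converted by overexpressing the muscle transcription factor Myf6 in the presence of forskolin, RepSox and CHIR99021. Colonies that no longer depended on the Myf6 vector were picked and expanded for 4 passages. A single library was made from each clone, so every value rests on 1 library per genotype, there are no replicates, and intervals cover counting error only. The WT library holds 8191 barcodes and 285232252 UMIs (median 34170 per barcode) and the KO library 7670 barcodes and 282739488 UMIs (median 37369). After filtering, 7313 WT cells with 278794522 UMIs and 5590 KO cells with 237498200 UMIs were compared.

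Myod1 (ENSMUSG00000009471), the targeted gene, was lower in the KO library but was not absent. Its level was 162 CPM (UMI counts scaled to the library total) in WT and 63.2 CPM in KO, from 45194 and 15005 UMIs, a KO/WT ratio of 0.390 (95% interval 0.383 to 0.397). The ratio was 0.344 after TMM scaling and 0.412 as a mean over cells. In WT the level differed by class, from 122 CPM in progenitor-like cells to 294 CPM in committed myocyte-like and 181 CPM in differentiated muscle-like cells. In KO it was 54.9, 88.4 and 69.0 CPM in these classes and 59.1 CPM in fibroblast-like cells, where WT, with 16 UMIs in 22 cells, was at 21.8 CPM (12.5 to 35.5). The labels do not say which part of the allele was deleted, so 3' tags may lie outside it, and the remaining UMIs do not check the knockout label.

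The first question of the design is how the other muscle regulators stood in the clone labelled MyoD-KO. Myf5, the closest relative of MyoD and a marker of myoblast determination, was higher in KO, at 60.0 against 16.7 CPM (ratio 3.60, 3.48 to 3.72). Myf6, the factor used for conversion and normally a late myotube gene, was also higher, at 24.2 against 5.30 CPM (ratio 4.57, 4.32 to 4.84). Myogenin (Myog), which drives terminal differentiation, was present in both clones at 407 CPM in KO and 307 CPM in WT (ratio 1.33, 1.31 to 1.34). Pax7, the satellite cell factor, was at 126 CPM in KO and 112 CPM in WT, a log2 ratio of 0.17 that became -0.01 after TMM scaling. Pax3, its embryonic relative, had 908 UMIs in KO (3.82 CPM) and 1 UMI in WT, a ratio of 1066 with a counting interval from 191 to 42146. The identifiers of these genes are ENSMUSG00000000435, ENSMUSG00000035923, ENSMUSG00000026459, ENSMUSG00000028736 and ENSMUSG00000004872, in this order. Myf6 UMIs of the gene and of the conversion vector could not be told apart in these files.

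Regulator levels differed by class in both clones. In progenitor-like cells Myf5 was at 91.7 CPM in KO and 22.8 CPM in WT, and Pax7 at 204 and 152 CPM. Pax7 is among the markers that named this class and, unlike the other regulators, was not left out of the clustering. Its levels by class are thus partly set by how cells were grouped. In committed myocyte-like cells Myog was at 1103 CPM in KO and 679 CPM in WT, where 1 of the 2 clusters had 1084 CPM. Pax7 was at 32.7 CPM in KO and 55.6 CPM in WT, where the 2 clusters had 77.0 and 22.5 CPM, so its direction depends on the WT cluster. In differentiated muscle-like cells Myf6 was at 99.6 CPM in KO and 28.1 CPM in WT, and Myog at 1098 and 978 CPM. Myog was at 704, 1338 and 1033 CPM in WT clusters 10, 13 and 15, so its direction here depends on the WT cluster too. With all deposited barcodes kept, the log2 ratio of Myog in the differentiated class was -0.10, against 0.17 as reported. Pax3 was at 5.43 CPM in KO progenitor-like cells (5.04 to 5.84) and 4.52 CPM in KO fibroblast-like cells (3.68 to 5.50), and at 2.02 and 0.347 CPM in the committed and differentiated classes of KO. The clusters behind these classes came almost wholly from 1 library each, as given with the classes.

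**Figure D1:**
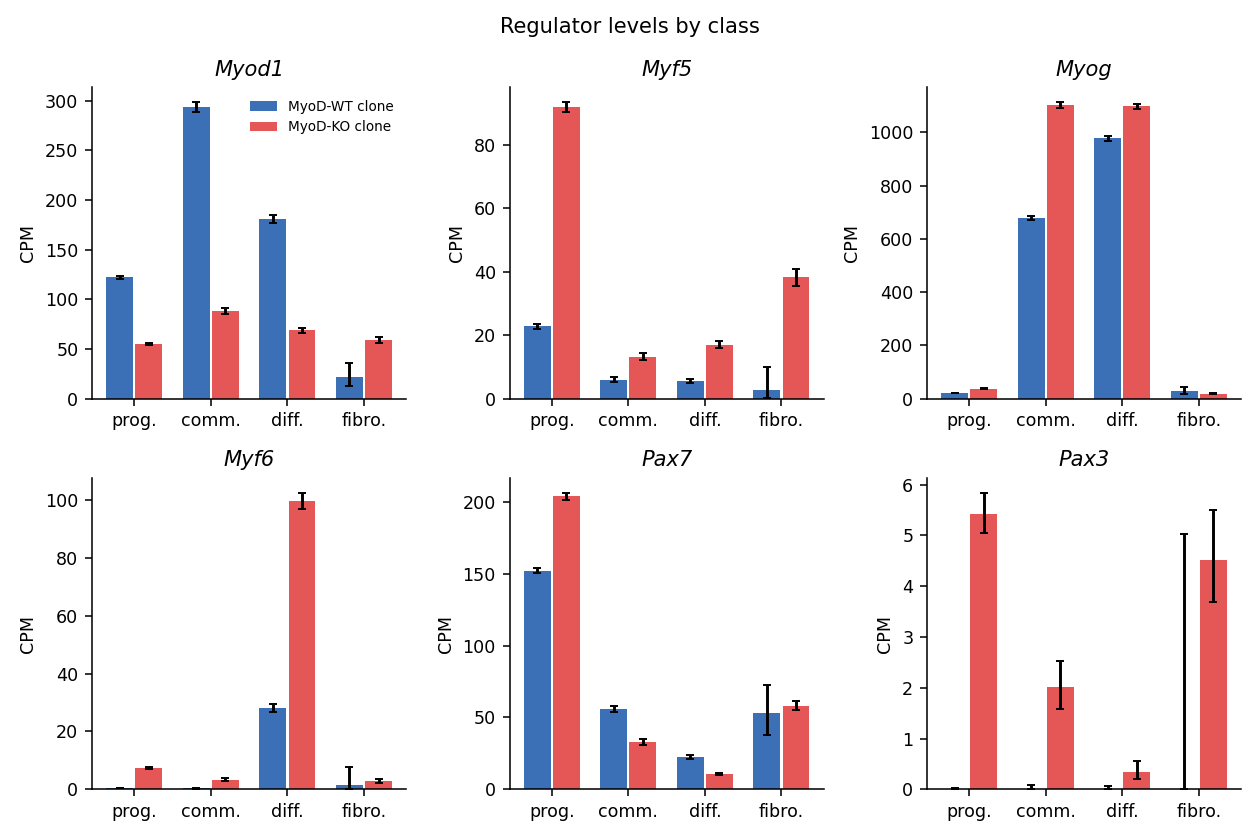
CPM of 6 regulators (vertical axes, each on its own scale) by class (horizontal axes: progenitor-like, committed myocyte-like, differentiated muscle-like and fibroblast-like) in the WT clone (blue) and the KO clone (red); whiskers are exact 95% Poisson intervals. Myod1 is lower in KO in the 3 muscle classes, Myf5 is highest in KO progenitor-like cells at 91.7 CPM, and Myf6 in KO differentiated muscle-like cells at 99.6 CPM.

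Shares of cells with at least 1 UMI were compared after thinning each cell to 5000 UMIs, which left out 80 shallower WT cells and 168 shallower KO cells. Myod1 was found in 48.4% of WT cells (47.2 to 49.5) and 24.4% of KO cells (23.2 to 25.5), and Myf5 in 7.51% and 22.9%. Myf6 was found in 2.17% and 7.80%, Myog in 34.9% and 36.7%, and Pax7 in 38.2% of cells in both libraries. Pax3 was found in 0 of 7233 WT cells, which allows up to 0.0415% of cells with a UMI at this depth and sets no limit on lower expression, and in 1.83% of KO cells. Without thinning the WT and KO shares were 90.1% and 78.2% for Myod1, 35.7% and 65.5% for Myf5, and 7.64% and 28.5% for Myf6. They were 60.3% and 68.3% for Myog, 77.6% and 71.0% for Pax7, and 0.0137% and 9.64% for Pax3. As a measure of free RNA, thinned Myog was found in 8.75% of KO fibroblast-like cells (median depth 36947 UMIs before thinning) against 90.6% of KO committed myocyte-like cells (median 42793). Shares at or below this one are not read as expression on their own. In the KO fibroblast-like cells Pax7 was found in 20%, Myf5 in 17.1% and Myod1 in 23.2%, all above Myog although Myog had the highest level of the 4 in the KO library, so free RNA in 1 ratio does not account for them. The Myod1 share of KO progenitor-like cells was 21.4% at a median depth of 39312.

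Cell classes were then compared, to ask whether the KO clone held the same kinds of cell. Both clones held progenitor-like, committed myocyte-like and differentiated muscle-like cells. Progenitor-like cells made up 65.7% of WT cells (64.6 to 66.8) and 55.9% of KO cells (54.6 to 57.2). Committed myocyte-like cells made up 16.8% and 14.3%, and differentiated muscle-like cells 16.2% and 18.5%. The differentiated cells included 221 KO cells of shallow cluster 14 (median 5398 UMIs) and 89 WT cells of shallow cluster 15 (median 9218 UMIs). Fibroblast-like cells made up 0.301% of WT cells (22 cells, 0.189 to 0.455) and 10.0% of KO cells (561 cells, 9.26 to 10.9). The WT share was 0.757% with the 6% highest doublet scores removed, 0.647% with all deposited barcodes and 0 with each library clustered on its own, when 763 WT cells led by Spp1, Car9 and Areg were named smooth muscle-like. The fibroblast-like cluster was led by Slpi, Spp1 and Crabp1 and by the growth factor genes Areg and Ereg, so it was named from its markers and not from its leading genes. Unnamed clusters held 0.957% and 1.29% of cells.

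The classes of the 2 clones were built from different clusters. Progenitor-like cells were clusters 1, 3, 6, 7 and 9 in WT and clusters 0 and 2 in KO, committed myocyte-like cells clusters 8 and 12 in WT and 5 in KO, and differentiated muscle-like cells clusters 10, 13 and 15 in WT and 4 and 14 in KO. Each of the 18 clusters took at least 93.3% of its cells from 1 library, so a cluster may stand for its library and not for a cell type, and genes that define clusters differ between the clones. Cluster 6 of the WT progenitor-like cells was led by the hypoxia gene Car9 and by the metallothioneins Mt1 and Mt2, and clusters 1 and 2 were led by cell cycle genes. With each library clustered on its own the progenitor-like share was 63.9% in WT and 66.0% in KO, reversing its direction, 890 WT cells in all were then named smooth muscle-like, and the committed share was 7.21% in WT and 4.42% in KO. Some of these names rested on narrow margins of the mean marker level. In WT, 763 cells scored 0.662 as smooth muscle-like and 0.659 as progenitor-like. In KO, 588 cells named progenitor-like scored 0.535 for that class and 0.531 as committed myocyte-like. With all deposited barcodes kept, the differentiated share was 15.1% in WT and 29.0% in KO.

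**Figure D2:**
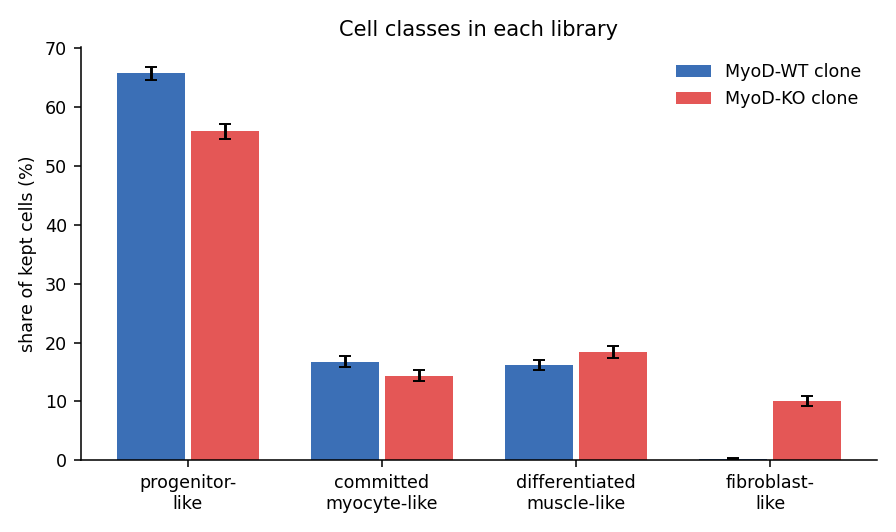
Share of kept cells (%, vertical axis) in each class (horizontal axis) for the WT clone (blue) and the KO clone (red); whiskers are exact 95% binomial intervals. Fibroblast-like cells make up 10.0% of KO cells and 0.301% of WT cells, and the 3 muscle classes are present in both.

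Across all cells the clones differed in many genes besides the muscle regulators. Of 8793 genes with at least 10 CPM in the higher library, 1169 were at least 2-fold higher and 296 at least 2-fold lower in KO, so that 79.8% of them were higher. TMM scaling moved the median log2 ratio of these genes from 0.08 to -0.10, and 924 genes were then higher and 471 lower, with 66.2% higher. Among the 12 genes furthest up were Igfbp6, which encodes an IGF-binding protein and was at 63.7 CPM in KO and 0.226 in WT, and Crabp1, a retinoic acid-binding protein gene, at 134 and 0.735 CPM. The protease inhibitor gene Slpi was at 567 and 3.48 CPM, osteopontin (Spp1) at 2320 and 34.0 CPM, galectin-3 (Lgals3) at 493 and 5.00 CPM, and S100a4, a calcium-binding protein gene of motile mesenchymal cells, at 398 and 3.27 CPM. Serpinb1a, Hecw2, Myo16, Pcdh15, Cav1 and Ly6e completed the 12, with log2 ratios from 5.60 to 6.34. With the fibroblast-like cells left out, the log2 ratio of Crabp1 was 3.22 against 7.51, of Slpi 5.66 against 7.35 and of Spp1 4.29 against 6.09, while that of S100a4 was 7.18 against 6.93.

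Alx1, a homeobox gene of craniofacial mesenchyme, was furthest down, at 86.1 CPM in WT and 0.0168 CPM (4 UMIs) in KO. The adhesion genes Adgrl3 and Cntn5 were at 65.4 and 65.3 CPM in WT and at 0.147 and 0.901 CPM in KO. The imprinted gene Nnat was at 441 and 22.8 CPM in WT and KO, the scaffold gene Grip1 at 615 and 65.7 CPM, and the calcium release channel gene Ryr3 at 332 and 41.3 CPM. St6galnac3, the micropeptide gene Mrln, Cited1, Fbn2, Bmpr1b and Clstn2 had log2 ratios from -2.87 to -2.51.

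**Figure D3:**
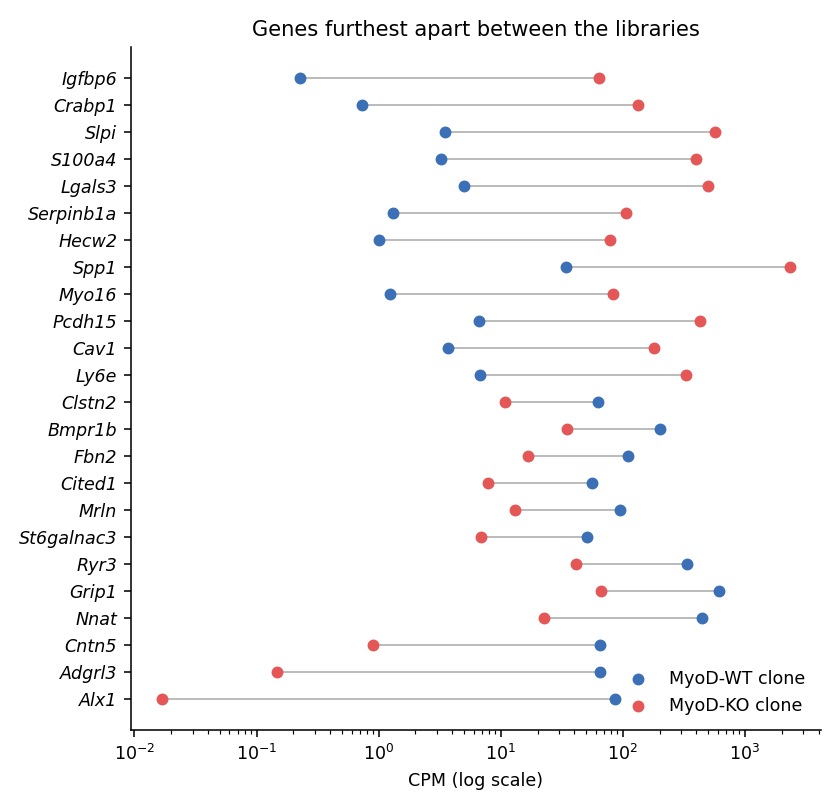
CPM (horizontal axis, log scale) in the WT clone (blue) and the KO clone (red) of the 12 genes furthest up and the 12 furthest down in KO (vertical axis). Igfbp6 has the highest log2 ratio, 8.14, and Alx1 the lowest, -12.32.

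Fixed gene lists were used to ask which programmes the 2 clones differed in. Of 36 lists, 14 stood apart as higher in KO and 5 as lower, against random lists matched on expression. Muscle lists were among the higher ones. Of 18 genes of adult fibres and their metabolism, 11 were at least 2-fold higher in KO and none lower, with a median log2 ratio of 1.90. Fast myosin Myh1 was at 596 CPM in KO and 81.5 CPM in WT, creatine kinase Ckm at 208 and 34.3, and Myh4 at 71.6 and 13.5. Of 41 sarcomere genes, 10 were higher and 2 lower (median 0.39): Myom2 was at 71.9 and 21.9 CPM, but slow troponin Tnnt1 was lower in KO, at 180 against 733 CPM, and so was the myosin chaperone gene Smyd1, at 19.1 against 61.7 CPM. Commitment and fusion genes had a median of 0.57, with 4 of 17 higher, among them the cell cycle inhibitor Cdkn1c (2973 CPM in KO and 931 in WT) and Hes6 (230 and 83.9). Known MyoD targets had a median of 0.58, with Ckm, Des and Acta1 higher and none of 16 lower, and 3 of these genes also belong to the sarcomere or fibre lists. Within differentiated muscle-like cells the MyoD target list did not stand apart (median 0.04, 51.2th percentile), with 3 genes higher and 1 lower.

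The satellite cell and fibroblast matrix lists also stood apart as higher in KO, although most satellite cell genes did not pass the size rule. Satellite cell genes had a median of 0.56, with 5 of 20 higher and 2 lower: the adhesion gene Vcam1 was at 30.8 CPM in KO and 0.0825 in WT and the Notch target Heyl at 66.1 and 14.4, whereas the repressor gene Msc was lower, at 12.7 against 52.6 CPM. Fibroblast matrix genes had a median of 1.81, with 11 of 21 higher and none lower, including Col6a3 (231 CPM in KO and 6.46 in WT), Fbln2 (27.9 and 0.316) and Dcn (16.2 and 0.387). With the fibroblast-like cells left out the median was 0.71, and the log2 ratio of Dcn was 1.28 against 5.39, while Col6a3 (5.28 against 5.16) and Fbln2 (6.16 against 6.47) stayed close. Of 4 measured cartilage and bone genes only the osteoblast factor Runx2 was past the size rule, at 26.1 against 2.08 CPM (list median 2.70, but 0.55 and within the range of random lists with no expression minimum). The bHLH inhibitor list had a median of 0.60, with Twist2 at 17.0 CPM in KO and 0.161 in WT and Bhlhe40 at 31.1 and 8.81, but only 0.15 when members below 10 CPM were left out, and the log2 ratio of Twist2 was 3.76 against 6.72 without the fibroblast-like cells.

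Several lists of growth arrest and stress genes stood apart as higher in KO over all cells, though cell cycle exit genes and p53 targets did not in every class. Of 14 cell cycle exit genes, 4 were higher and none lower (median 0.62): the p16 and Arf locus Cdkn2a was at 389 CPM in KO and 120 in WT, Cdkn2b at 43.2 and 5.08, and Btg2 at 162 and 29.4. Of 16 p53 target genes, 5 were higher and none lower (median 0.77), with Mdm2 at 143 and 47.6 CPM, Phlda3 at 453 and 132, and Trp53inp1 at 45.5 and 5.50. Of 17 immediate early genes, 9 were higher and none lower (median 2.01), with Fos at 73.1 and 11.6 CPM and Ier3 at 63.0 and 2.40 (log2 ratio 4.72, or 4.06 without the fibroblast-like cells). Interferon-linked genes (3 of 7 higher, median 1.82) included Ifitm3 at 276 and 14.8 CPM, and antigen presentation genes (4 of 8 higher, median 3.42) included H2-K1 at 17.4 and 1.86 CPM. Only 5 of these 8 reached 10 CPM, and the antigen presentation list summed to 183 CPM in KO and 71.4 in WT. In differentiated muscle-like cells 0 of its 5 measured members passed the size rule, with sums of 74.5 and 60.1 CPM, although its median was 2.30. Hypoxia and glycolysis genes had a median of 0.96, with 5 of 13 higher and 1 lower, the glucose transporter Slc2a1 at 50.5 and 11.7 CPM and the hexokinase Hk2 lower, at 41.4 against 94.0 CPM. By class, cell cycle exit genes stood apart in progenitor-like cells (median 1.19) but not in committed (0.39) or differentiated cells (0.22). For p53 targets the medians were 0.85, 0.65 and 0.28 in this order, and only the last did not stand apart. The immediate early, interferon-linked, antigen presentation and hypoxia and glycolysis lists stood apart as higher in every class compared.

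The lower lists were S phase, G2M phase, Wnt target, neural and Y-linked genes. S phase genes had a median of -0.32 and G2M genes of -0.31, but only 1 of 42 and 2 of 52 were at least 2-fold lower, among them the chromatin gene Hmgb2 at 341 CPM in KO and 852 in WT. Wnt target genes had a median of -0.62 and went both ways, with 3 of 10 lower and 1 higher: Rnf43 was at 0.341 against 12.1 CPM, Lgr5 at 32.1 against 145 and Lef1 at 13.3 against 55.0, but Ccnd1 was higher, at 232 against 58.5 CPM. The 6 measured neural genes were all below 10 CPM (median -0.94), and with no minimum their median was 0.00 and did not stand apart. The Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y summed to 186 CPM in WT and 1.65 CPM in KO.

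Other lists did not stand apart. Smooth muscle genes had a median of 0.12, but Tagln (46.1 CPM in KO and 253 in WT), Acta2 (306 and 814), Actg2 and Synpo2 were at least 2-fold lower and none was higher, and the median was -1.29 over members with at least 10 CPM. TGF-beta target genes (median 0.60), cAMP target genes (0.31), Notch genes (-0.09) and unfolded protein response genes (0.39) were within the range of random lists, although the cAMP list held Areg, an EGF-family growth factor gene, at 142 CPM in KO and 3.56 in WT (log2 ratio 5.32, or 3.21 without the fibroblast-like cells). Calcium handling genes (0.16), acetylcholine receptor and junction genes (0.23), muscle regulators (0.20), tendon genes (0.14), adipocyte genes (-0.61) and the imprinted genes (-0.15) were within it too. Endothelial, immune, epithelial and pluripotency lists had fewer than 3 members measured and were not ranked.

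**Figure D4:**
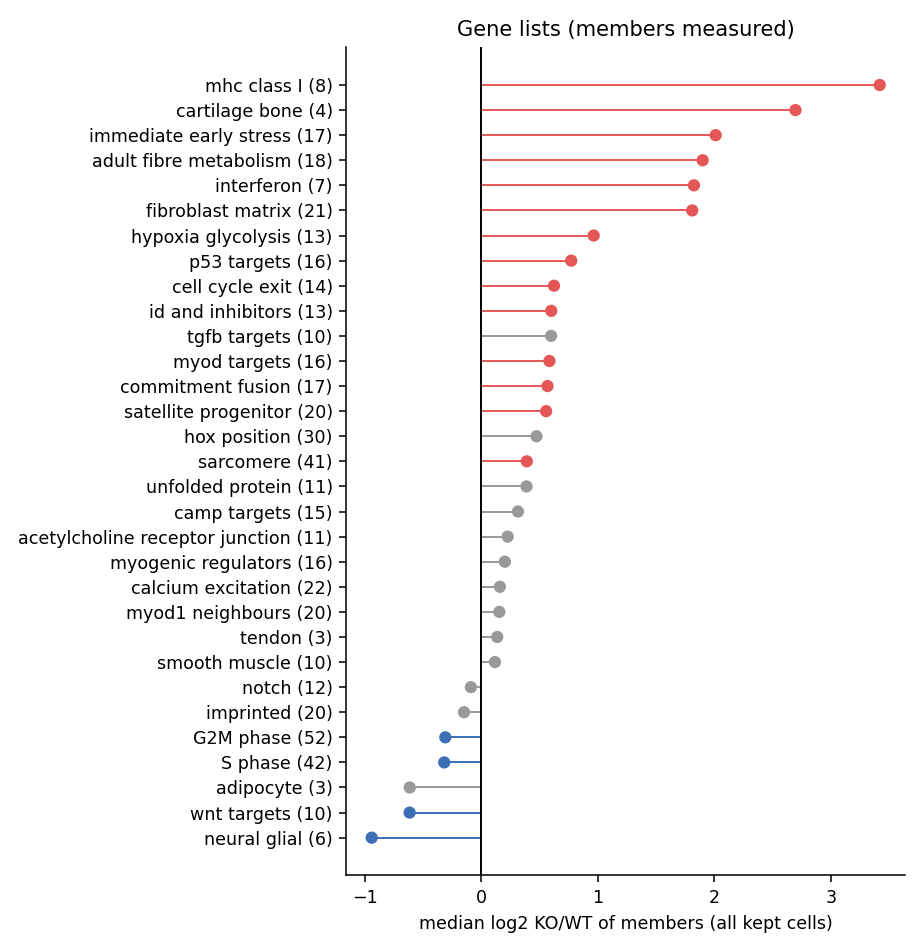
Median log2 KO/WT ratio (horizontal axis) of the members of each fixed list (vertical axis, members measured in brackets) over all kept cells; red lists stood apart as higher, blue lists as lower, and grey lists did not. The Y-linked list is not drawn, and antigen presentation genes have the highest median, 3.42, with 5 of 8 members at 10 CPM or more.

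Within progenitor-like cells (WT clusters 1, 3, 6, 7 and 9, KO clusters 0 and 2), growth arrest genes were higher in KO and sarcomere genes went both ways. Cdkn1c was at 2876 CPM in KO and 456 in WT, Btg2 at 182 and 19.2, and Cdkn2a at 418 and 117, and 8 of 14 cell cycle exit genes were higher (median 1.19). Vcam1 was at 46.3 and 0.0557 CPM and Heyl at 101 and 19.7, but the calcitonin receptor Calcr, a quiescence gene, was lower, at 0.295 against 14.0 CPM. Heyl and Calcr are also among the markers that named the class. The cell cycle gene Ccnd2 was at 282 CPM in KO and 1.97 in WT. Of 35 sarcomere genes 5 were higher and 6 lower: Tnnt1 was at 37.5 against 408 CPM, Actc1 at 49.5 against 205 and Tpm1 at 266 against 858, while Acta1 was at 223 against 64.2 and Myl1 at 207 against 59.0. MyoD targets stood apart as higher (median 0.79), with 6 of 16 higher and 3 lower, and so did adult fibre genes (median 1.59), while commitment and fusion genes, with 5 of 17 higher and 1 lower, did not. Free RNA from differentiated muscle-like cells, where Acta1 was at 17506 CPM in KO and 6998 CPM in WT, was not excluded as the source of these higher muscle genes. Acetylcholine receptor and junction genes stood apart as lower (median -0.53), with 2 of 9 lower, among them Chrna1 at 10.0 against 34.5 CPM, but Chrnd was higher, at 87.4 against 31.1 CPM, and their sum was higher too, at 374 against 322 CPM. Of 8658 genes, 1148 were higher and 323 lower, 78.0% of them higher, or 880 and 552 (61.5%) after TMM scaling. The genes furthest up were Hecw2, Serpinb1a, S100a4, Lgals3, Ccnd2 and Pcdh15, and those furthest down Alx1, Cntn5, Cdh6, Man1a, Nnat and Grip1.

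Within committed myocyte-like cells (WT clusters 8 and 12, KO cluster 5), the KO class as a whole had more Myog and Cdkn1c but less of many contractile genes. WT cluster 8, whose marker scores lay close to those of progenitors, had 418 CPM of Myog, 77.0 of Pax7 and 626 of Top2a. WT cluster 12 had 1084, 22.5 and 89.6 CPM, against 1102, 32.8 and 259 CPM in KO cluster 5. Myog, Pax7 and cycling differences of this class thus depend on which WT cluster is compared. The KO class was mixed too: at resolution 1.2 it split into 564 cells, with marker scores close to those of progenitors, and 252 others. Levels in these KO parts were not compared with the WT clusters, so the unsplit KO cluster matches neither of them like for like. Cdkn1c was at 7127 CPM in KO and 1969 in WT. Of 39 sarcomere genes, 11 were lower and 2 higher (median -0.30, 0.01th percentile): Tnnt1 was at 173 against 898 CPM, Tpm1 at 306 against 1208, Tnnt3 at 98.6 against 320 and Smyd1 at 19.3 against 75.9. With the 6% highest doublet scores removed the median was -0.25 where the other cells kept their classes, and -1.34 where they were clustered again, which put other cells in the class. The MyoD partner gene Mef2c was at 134 against 363 CPM, Chrna1 at 30.7 against 159, Musk at 4.07 against 21.7 and the sarcoglycan gene Sgca at 1.36 against 13.3. The MyoD target and the commitment and fusion lists, which hold Mef2c, Chrna1 and Sgca, nevertheless stood apart as higher (medians 0.53 and 0.58), with 2 higher and 2 lower in the first and 4 higher and 1 lower in the second, and did so without the highest doublet scores where classes were kept (0.56 and 0.69) but not where cells were clustered again (0.15 and 0.19). The higher members include Ckm and Acta1, for which free RNA was not excluded here either. Sgca, Chrna1 and Cdkn1c are also among the markers that named this class, so these lists are partly read from the genes that chose its clusters. The G2M list stood apart as lower (median -0.61), with 7 of 52 genes lower, among them Ube2c at 163 against 431 CPM, and so did TGF-beta targets (median -1.03), with 2 of 8 lower and 1 higher. Of 8244 genes, 885 were higher and 359 lower, 71.1% of them higher, or 703 and 517 (57.6%) after TMM scaling. The genes furthest up were Tafa5, Lgals3, S100a4, Ccnd2, B3gat1 and Myo16, and those furthest down Adgrl3, Alx1, Nnat, Gfra1, Kcnc1 and Barx2.

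Within differentiated muscle-like cells (WT clusters 10, 13 and 15, KO clusters 4 and 14), KO cells had more adult fibre transcripts. Myh1 was at 2799 CPM in KO and 359 in WT, Ckm at 990 and 170, Ckmt2 at 38.5 and 4.18, and Acta1 at 17506 and 6998. Of 18 adult fibre genes 14 were higher and 1 lower (median 1.88). Sarcomere genes had a median of 0.39, at the 99.7th percentile, with 12 of 41 higher and Tnnt1 and Smyd1 lower, and many of these genes are also markers that named the class. This list no longer stood apart when the 6% of cells with the highest doublet scores were removed, whether the others kept their classes (median 0.26, 93.2th percentile) or were clustered again (0.15, 72.8th percentile). The S and G2M lists stood apart as lower (medians -1.06 and -1.48), with 14 of 42 and 29 of 52 genes lower, among them Bub1 at 1.78 against 11.5 CPM. With the highest doublet scores removed and classes kept these medians were -0.38 and -0.67. The share of cells called in G2M was then 1.63% in WT and 0.462% in KO, against 9.09% and 1.64% before, and in S phase 0.204% and 0.231%, against 1.90% and 0.436%. Pax7 then had a log2 ratio of 0.01, against -1.07. Most cycling calls of this class in WT thus lay in cells with high doublet scores, and whether these were doublets was not tested. Of 13 hypoxia and glycolysis genes 9 were higher (median 1.29), with Egln3 at 127 against 30.2 CPM. The imprinted list stood apart as lower (median -0.53), with 5 of 21 lower, among them Plagl1 at 23.4 against 101 CPM, and 1 higher. Of 7826 genes, 806 were higher and 635 lower, 55.9% of them higher, but 746 and 1042 (41.7%) when mitochondrial and ribosomal protein genes were left out of the total. The genes furthest up were Slpi, Serpinb1a, S100a4, Agbl1, Lgals3 and Nrxn3, and those furthest down Adgrl3, Nnat, Fign, Naaladl2, Ripor2 and Il17b. Slpi, at 62.6 CPM in KO, also led the KO fibroblast-like cluster. Its log2 ratio of 6.25 was 3.97 with the highest doublet scores removed and classes kept, and 3.47 with the cells clustered again, below Serpinb1a (5.70 and 5.57), so RNA of the fibroblast-like cells or doublets with them were not excluded as its source.

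Cell cycle phases were compared to ask whether the clones cycled alike. After thinning, 24.3% of WT cells (23.3 to 25.3) and 15.7% of KO cells (14.7 to 16.7) were called in S phase, and 49.0% (47.8 to 50.1) and 34.7% (33.4 to 36.0) in G2M. Without thinning the S phase shares were 24.9% and 15.9% and the G2M shares 49.4% and 33.8%. The summed S phase list was at 2486 CPM in WT and 2002 CPM in KO, and the G2M list at 6480 and 4968 CPM. In progenitor-like cells 32.2% of WT and 21.4% of KO cells were called in S phase and 59.0% and 51.6% in G2M, where the S phase list stood apart as lower (median -0.21), while the G2M list there had a median of -0.04 and Mki67 was higher in KO, at 243 against 175 CPM. In committed myocyte-like cells 47.3% of WT and 24.1% of KO cells were called in G2M but 15.4% and 15.9% in S phase, and Top2a was at 416 and 259 CPM. Phase calls read free RNA as well, and cycling is not read from them alone.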

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

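Sarcomere genes and 3 single genes differed between the clones in opposite directions in different cell classes, and KO barcodes left out of the comparisons were rich in muscle transcripts. The gene lists were fixed before the data were examined, while the removal of the highest doublet scores, the comparison of directions between classes and the tests of explanations were chosen after the results were seen. Differences between classes were not tested, since each genotype has 1 library, and each class rests on different clusters in the 2 clones.

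The sarcomere list had a median log2 KO/WT ratio of -0.30 in committed myocyte-like cells and of 0.39 in differentiated muscle-like cells, and stood apart from random lists in both. With the 6% highest doublet scores removed and the other cells left in their classes, these medians were -0.25 and 0.26, and with the other cells clustered again -1.34 and 0.15. The second no longer stood apart in either case. The Notch receptor gene Notch1 had a log2 ratio of 1.07 in progenitor-like and -1.05 in differentiated muscle-like cells. The antiproliferative gene Btg1 had 1.49 and -1.11, and the imprinted Notch-like gene Dlk1 1.51 and -1.10, in the same order. The directions of these 3 genes were the same with the highest doublet scores removed, at -1.08 for Notch1, -1.34 for Btg1 and -1.22 for Dlk1 in the differentiated class with classes kept, and at -0.99, -1.18 and -1.21 with the cells clustered again. Every other list that stood apart in more than 1 class did so in 1 direction.

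Barcodes removed for having under 1000 genes although their mitochondrial share was within the limit made up 9.14% of KO barcodes (701) and 1.70% of WT barcodes (139). The sarcomere list summed to 90278 CPM in these KO barcodes (95% interval 89655 to 90904) and to 84950 CPM (83556 to 86361) in the WT ones, against 24617 and 16808 CPM in kept KO and WT cells. A further 777 KO barcodes and 296 WT barcodes had enough genes but over 15% mitochondrial UMIs, and held the list at 105736 and 49949 CPM. Their median depth was 35350 UMIs in KO and 12795 in WT, against 40353 and 35512 in kept cells. The filters thus took out more barcodes rich in sarcomere transcripts from the KO library than from the WT library, and the share of differentiated cells depends on them. Gene levels within that class may depend on them too, and the direction of Myog there changed with all deposited barcodes kept.

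The first pattern weighed is the Myod1 signal of the KO library. Carry-over of cells or RNA from the WT clone would bring its Y-linked transcripts, but their sum in KO was 0.887% of the WT level, against 39.0% for Myod1. Free RNA from other KO cells would keep Myod1 and Myog in 1 ratio, but in fibroblast-like KO cells Myod1 stood at 93.6% of the library level and Myog at 4.36%. A transcript of the targeted allele that keeps the counted 3' end may remain, with 54.9 CPM in the class where it was lowest. This stays open, because the deleted part is not given and 3' tags do not show the protein. The label MyoD-KO does not give the number of altered copies either, so a remaining unaltered copy was not excluded.

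The second is the fibroblast-like share of 10.0% in the KO clone. Doublets would be deeper than other cells, but the median depth of these cells was 0.915 times that of kept KO cells. WT cells mixed in would carry Y-linked transcripts, but these stood at 0.731% of the WT level in the KO library's fibroblast-like cells. Loss of MyoD and a difference between single clones cannot be told apart, with 1 clone per genotype, and either may underlie the share.

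The third is Kcnc1, a potassium channel gene next to Myod1 in the reference order, chosen after its values were seen. It was at 1.40 CPM in KO and 32.3 CPM in WT, a ratio of 0.0434. Loss or silencing of the region as a whole would lower its neighbours too, but Otog on the near side was at 6.14 against 6.13 CPM and Sergef on its far side at 34.5 against 37.6 CPM, and the other 19 measured genes of the fixed list around Myod1, which reaches past the nearest 10 on each side, had a median log2 ratio of 0.16. Of the weakly expressed genes close by, Ush1c was lower in KO, at 0.0126 against 0.183 CPM, and Abcc6 at 0.0463 against 0.499 CPM, so silencing of single genes stays open. Shares of classes do not account for it, because the highest ratio within a class was 0.103. An effect of the altered allele on its neighbour, the missing protein and the choice of clone cannot be told apart. There is 1 clone per genotype, the label MyoD-KO does not give the number of altered copies, and reads were not assigned to copies. Each may contribute to the ratio of 0.0434.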

How the results depend on the processing

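Alternatives that removed the highest doublet scores, the fibroblast-like class or the shallow clusters, and class shares over all deposited barcodes, were chosen after seeing the data, and the others before the data were examined. No paired analysis was possible because each genotype has 1 library. The cause of each shift below was not tested unless the alternative's own construction gives it.

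Over all cells, 306 of 315 list medians kept their place inside or outside the range of random lists. Among lists inside it, calcium handling, smooth muscle, tendon, junction, adipocyte, Notch, imprinted and Myod1 neighbour genes changed the sign of their median under some alternative, so no direction is read from them. With all deposited barcodes, calcium handling genes stood apart (0.42). With members of at least 10 CPM, smooth muscle genes (-1.29) and position genes (0.92) stood apart and bHLH inhibitors (0.15) no longer did. With no minimum, smooth muscle (-0.73) and position genes (0.98) stood apart, cartilage and bone genes (0.55) did not, and the neural median was 0.00. With a total free of mitochondrial and ribosomal protein genes, position genes stood apart (0.76).

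TMM scaling gave 471 lower genes over all cells and 552 in progenitor-like cells, and a Myod1 ratio of 0.344. The mean of the cells' own CPM gave a Myod1 ratio of 0.412. A total without mitochondrial and ribosomal protein genes gave 1042 lower genes in differentiated muscle-like cells. Other minimums change how many genes are compared. At 50 CPM, the higher and lower genes numbered 365 and 125 over all cells, 343 and 135 in progenitor-like, 284 and 144 in committed myocyte-like and 299 and 222 in differentiated muscle-like cells. With no minimum they numbered 4676 and 1370, 4582 and 1307, 3528 and 1254, and 3016 and 2312.

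Class shares are given as KO minus WT in percentage points. The progenitor-like difference of -9.86 was -7.45 at resolution 0.4, -7.96 at 1.2, -12.0 with the highest doublet scores removed and -18.3 with all barcodes, and reversed to 2.05 with each library clustered on its own. In that last setting some class names were decided by narrow margins, as given with the classes. The committed difference of -2.42 was -4.31 at resolution 0.4 and -3.98 with all barcodes. The differentiated difference of 2.22 was 5.71 with the highest scores removed and 13.8 with all barcodes. It rests in part on shallow clusters, which held 221 KO and 89 WT cells of this class. The share was not taken without them, so its direction is not read. The fibroblast-like difference of 9.73 was 7.67 at resolution 1.2 and 7.25 with all barcodes.

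Thinning sets how many cells show a UMI. Thinned to 2000 UMIs, the KO minus WT differences were -12.7 points for Myod1, 6.62 for Myf5, 3.01 for Myf6, 2.20 for Pax7, 0.698 for Pax3 and -6.50 for S phase. Without thinning they were -11.8 for Myod1, 29.8 for Myf5, 8.0 for Myog, 20.8 for Myf6, -6.68 for Pax7 and 9.63 for Pax3. The Pax7 difference as reported, -0.05, lay within counting error, so its direction was not read.

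With the highest doublet scores removed, the other cells were clustered again or kept in their classes. In differentiated muscle-like cells the Notch list then reversed to 0.22 and 0.23 and the Pax7 difference to 0.343 and 0.609 points, in this order, and with classes kept the Pax7 log2 ratio reversed to 0.0105 and the S phase difference to 0.0275 points. Of 217 list medians within classes, 205 kept their place. Clustered again, commitment (0.19), S phase (-0.04), Wnt target (-0.21) and MyoD target genes (0.15) in the committed class and sarcomere genes in the differentiated class (0.15) no longer stood apart, and calcium handling genes in the committed class did (-0.64). With classes kept, sarcomere genes in the differentiated class (0.26) no longer did, and cell cycle exit genes in the committed class (0.42) and smooth muscle (-0.60) and cAMP target genes (0.64) in the differentiated class did. Of 1588 log2 ratios of named genes, 869 stayed within their counting interval. Others that changed sign, of Pax7, Tnc and Fcer1g over all cells, Myog in the differentiated and Dlk1 in the committed class, were not past the size rule. Depth limits rare transcripts such as Pax3, with 1 UMI in WT.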

Other observations

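Genes that mark body position differed between the clones. Of the HoxA genes, 4 were higher in KO by the size rule: Hoxa10 was at 16.1 CPM against 0.0108 CPM in WT, Hoxa9 at 20.9 against 0.147, Hoxa7 at 32.8 against 4.76 and Hoxa5 at 13.1 against 0.972. Hoxc8 was lower, at 8.18 against 24.6 CPM. Of 30 measured position genes 7 were at least 2-fold higher and 1 lower in KO, with a median of 0.47 that did not stand apart over all cells, but did over members of at least 10 CPM (0.92), with no minimum (0.98) and with a total free of mitochondrial and ribosomal protein genes (0.76). In differentiated muscle-like cells the list stood apart as higher, with a median of 0.85.

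Of 20 measured imprinted genes 2 were higher and 1 lower in KO. Ndn, which encodes necdin, was at 39.3 CPM in KO and 2.08 in WT, and Nnat at 22.8 and 441 CPM.

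The sex chromosome genes of the clones differed. Eif2s3y had 18290 UMIs in WT and 0 in KO, and Uty 12552 and 3. Of their X-linked counterparts, Kdm6a was at 40.7 CPM in KO and 27.6 in WT (ratio 1.47), Kdm5c at 64.3 and 42.5 (1.51), Eif2s3x at 105 and 82.3 (1.28) and Ddx3x at 132 and 129 (1.03). Xist is not listed in the files. The labels give no sex for either clone, and loss of the Y chromosome in a male clone was not excluded, so the sex of the KO clone stays open.

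Of other genes close to Myod1 in the reference order, Saal1 was at 20.7 CPM in KO and 22.3 in WT, while Emp3, further away, was at 236 and 64.0 CPM.

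The 22 fibroblast-like WT cells carried Y-linked transcripts at the level of their own clone, with Ddx3y at 45.0 CPM against 55.3 CPM in all WT cells.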
